A study of Rattus norvegicus with 4 samples.

How the data were processed

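Gene expression was measured on 4 single-colour microarrays, 1 for each of 4 cultures of primary rat cortical astrocytes, so each group held 1 array and there were no replicates. Per the labels' protocols, total RNA was extracted with Trizol, and sense-strand cDNA was fragmented and labelled with biotin by terminal transferase before hybridisation. The deposited table holds 1 value per probe and array, and its values were taken as log2 signal because they run from 1.14 to 13.4, as summarised values of such arrays do; neither the log base nor the unit is stated in the table or the labels. The background correction, probe summary and normalization that the authors applied are not given in the sources used here. The values were not exactly quantile normalized over these probes, since the array medians ran from 5.79 to 5.87 and the upper quartiles from 7.69 to 7.76. All folds given here rest on the log2 reading of the table.

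The table has 29489 probes. The probe annotation used here gives 1 gene symbol to 18511 of them, several to 575 and none to 10403, and the last 2 kinds were not named. Of the 18511 probes with 1 symbol, 18394 had an Entrez identifier found in the RefSeq gene table for rat assembly GRCr8, which supplied the current symbol. Where a gene had several probes (345 probes beyond the first), the probe with the highest mean over the 4 arrays stood for it, which left 18166 genes. Genes whose highest value over the 4 arrays reached 5.83, the median of all values of the table, were kept, which left 11790 genes. No detection call or background level was used here, so values below that median may sit at the background of the arrays.

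Each comparison is the difference of log2 values between 2 arrays. A gene was counted when that difference reached 2-fold in either direction. With 1 array per group no p-value, standard deviation or confidence interval between conditions can be given, and a difference between conditions cannot be told from a difference between single cultures or single arrays. The 3 main comparisons were IFN-γ against no treatment, IFN-γ with GW against IFN-γ alone (both with control siRNA), and SHP siRNA against control siRNA (both with IFN-γ and GW). The other 3 differences among the arrays were secondary.

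In total 21 gene lists (pathways, receptor targets, cell type markers and reference genes) were fixed before the data were examined. A list was summarised when at least 5 of its genes passed the filter, which held for 19 lists, so 57 list medians were looked at over the 3 main comparisons. Each median is given with its percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression with random seed 1. A list is called high or low when it lies outside the middle 95% of the random lists. This percentile describes these arrays and is not a test between conditions.

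Differences that share an array share its measurement error, with opposite signs where it is added in one and subtracted in the other, and with the same sign otherwise. Sets of genes were therefore chosen on 2 arrays and followed in the other 2, and correlations across genes were computed for pairs of differences with no array in common, 1 of which was added after the data were examined. Correlations of pairs that share an array are given beside a simulation of 100 tables of 4 unchanged arrays, with noise set from the robust spread of the IFN-γ difference, and their covariances with the noise of each main comparison in turn, a simulation added after the data were examined. Sets followed from IFN-γ to GW and from GW to SHP siRNA in the opposite direction are given beside 100 simulated tables with noise set from the GW difference. That noise was added to the measured values, which were taken as true. Other overlaps that share an array were not simulated.

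The genes named in the text were set by a rule written before the data were examined. For each main comparison it takes the 12 highest and 12 lowest differences of at least 1.5-fold among genes past the filter, leaving out provisional, olfactory, vomeronasal and taste receptor and small RNA symbols. It adds, for each list and comparison, up to 4 members with the greatest size of difference. It also adds the genes that the siRNA label could mean (Nr0b2, Ptpn6, Ptpn11), the receptor genes Nr1h2, Nr1h3 and Nr1h4, and the IFN-γ receptor genes Ifngr1 and Ifngr2. Genes named outside the rule are said to be so.

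The alternatives tried were quantile normalization, centring of each array on its median over genes past the filter, cyclic loess, no filter, a filter on the mean over the 4 arrays, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, the mean of a list in place of its median, and sets chosen on a shared array. A set without the immediate early list was added after seeing the data. A pseudocount planned for linear values was not needed. Quantile normalization and cyclic loess used limma 3.58.1 in R 4.3.3, and all other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

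The counting step was tested on simulated tables of 11790 genes with the noise of each comparison. In the tables made for IFN-γ, GW and SHP siRNA, it called 100%, 96.0% and 100% of 50 genes set at 2.83-fold, and 0%, 2.00% and 0% of 50 genes set at 1.5-fold. Of 11590 genes with no difference it called 0, 2 and 0. The noise was equal in all genes, with an SD per array of 0.111, 0.194 and 0.131 log2, so few such calls were built in. Greater noise at low signal and differences between single cultures were not simulated. These rates therefore check the calculation and are not error rates of the calls in these arrays. In the list step, run on the table for IFN-γ, 9 of 200 random lists of 20 genes lay outside the middle 95%. All 200 lay above it after a log2 shift of 0.30 was added. This too checks only the calculation, since random lists were set against random lists.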

Results

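The series asks, per its labels, how astrocytes transfected with an siRNA against SHP respond to interferon-γ (IFN-γ) in the presence of a compound the labels call GW. Astrocytes are the star-shaped glial cells of the brain, and IFN-γ is a cytokine that lymphocytes release in inflammation. The cells were primary cultures from the cerebral cortex of Sprague-Dawley rat pups aged 1 day, kept in serum-free medium before use to remove microglia and meningeal cells. There were 4 cultures with 1 array each. A control siRNA was used in an untreated culture, a culture with IFN-γ, and a culture with IFN-γ and GW. The SHP siRNA was used in a culture with IFN-γ and GW, and treatment lasted 3 h. SHP siRNA without GW, and GW without IFN-γ, were not analysed here. Each condition was measured once, so the differences below have no replicate check and describe these cultures. The number of arrays limits the precision.

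The 4 arrays were alike in scale, with median log2 values of 5.79, 5.80, 5.87 and 5.85 over 29489 probes in the order above. Across probes, which are not independent replicates, the untreated and IFN-γ arrays correlated at 0.992 and both GW arrays at 0.993. The untreated and IFN-γ with GW arrays, at 0.986, were the least alike of the 6 pairs.

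Nr0b2, which encodes the nuclear receptor small heterodimer partner, had log2 values of 5.33, 5.14 and 5.20 in the 3 cultures with control siRNA. It had 3.45 in the culture with SHP siRNA, 3.35-fold lower than in the control siRNA culture with the same treatment. None of the 500 genes nearest to it in level had so low a difference (0 of 500). All 4 values lay below the table median of 5.83, where the background of the arrays is unknown, so the fold is uncertain. The phosphatase genes Ptpn6 and Ptpn11, whose proteins are also abbreviated SHP, differed by -0.08 and 0.14 between those cultures. The liver X receptor genes Nr1h2 and Nr1h3 stood at 9.79 and 8.26 in the untreated culture and at 9.36 and 7.80 with IFN-γ and GW. The farnesoid X receptor gene Nr1h4 stayed below 5.83 in all 4 arrays, between 4.61 and 5.09. The IFN-γ receptor genes Ifngr1 and Ifngr2 stood at 9.83 and 8.81 in the untreated culture.

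**Figure D1:**
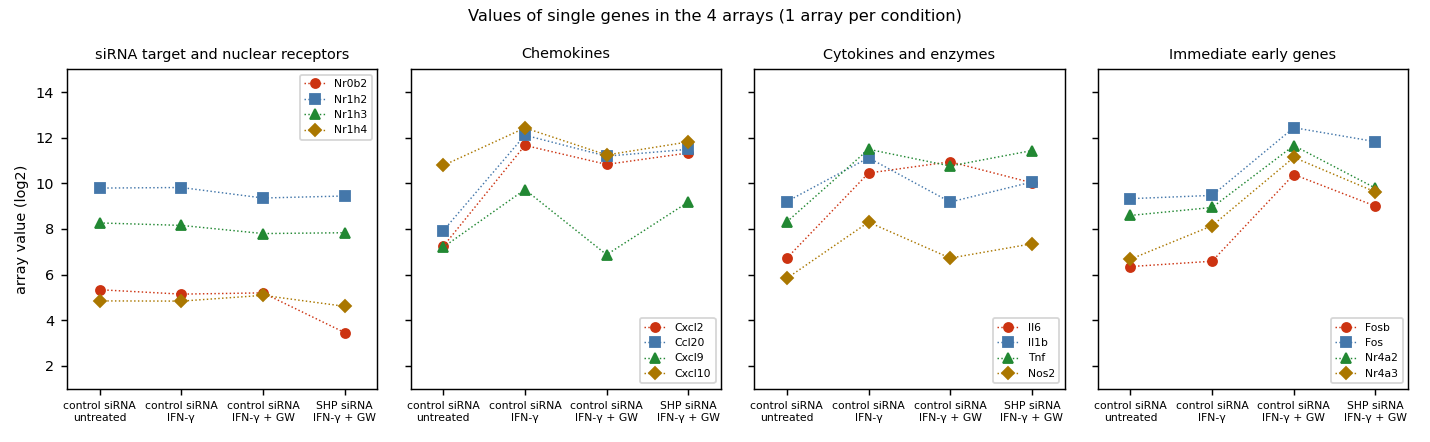
Log2 array values of 16 genes in the 4 cultures (x axis, 1 array per condition, dotted lines only join the points of a gene). Nr0b2 is at 3.45 with SHP siRNA and between 5.14 and 5.33 elsewhere, and Cxcl9 is at 6.87 with IFN-γ and GW but at 9.73 and 9.18 on either side of it.

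With IFN-γ the astrocyte culture held far more transcripts of chemokines and inflammatory cytokines than the untreated culture. The neutrophil chemokine gene Cxcl2 was 21.5-fold higher and Ccl20, which attracts CCR6-bearing lymphocytes and dendritic cells, 18.2-fold higher. The cytokine genes Il6, Tnf and Il1a were 13.3-fold, 9.08-fold and 7.10-fold higher, and the type I interferon gene Ifnb1 was 9.18-fold higher. Of 11790 genes, 190 were at least 2-fold higher and 34 at least 2-fold lower. Most genes differed little, and the middle 95% of differences lay between -0.48 and 0.67 log2.

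The other leading genes were Rtp3 (log2 difference 3.87), the atypical chemokine receptor gene Ccrl2 (3.82), the activation marker Cd83 (3.05), the chemokine receptor gene Cxcr5 (3.02), the niacin receptor gene Hcar2 (2.97) and the small Maf gene Maff (2.82). The lowest differences included the nucleotide receptor gene P2ry6 at -1.69, the Ras-related gene Rasd1 at -1.65, Nfam1 at -1.54, Ripply2 at -1.39 and Lrrc25 at -1.38. They also included the G protein-coupled receptor genes Gpr31 (-1.35), Lpar5 (-1.34) and Gpr18 (-1.25), the ubiquitin ligase gene Marchf1 (-1.30), the DNA demethylation gene Tet1 (-1.27) and the Toll-like receptor homologue gene Cd180 (-1.27). Ifnb1, Ccrl2 and Cxcr5 in the untreated culture and Ripply2, Lpar5, Marchf1 and Tet1 with IFN-γ lay below 5.83, so the size of their differences is uncertain.

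Chemokine and leukocyte adhesion genes were higher as a group. Of 17 past the filter, 14 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.77, above all 10000 random lists. Examples were Cxcl2 (4.43), Ccl20 (4.19), Ccl4 (2.73) and Cxcl9 (2.53), while Ccl5 differed by -0.13. Of 28 NF-κB-associated cytokine and enzyme genes, 20 were at least 2-fold higher and 0 lower, with a median of 1.64, also above all random lists. Nos2, the inducible nitric oxide synthase, went from 5.83 to 8.30, Ptgs2, which makes prostaglandin precursors, from 8.45 to 11.14, and Tnfaip2 differed by 2.47.

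Genes of interferon signalling were higher by less. In that list 4 of 23 were at least 2-fold higher, with a median of 0.29 above all random lists. The 4 were the transcription factor genes Irf1 (2.63) and Irf8 (1.01) and the feedback inhibitor genes Socs1 (1.90) and Cish (1.08). Of 9 genes for guanylate-binding proteins and immunity-related GTPases, which act against intracellular pathogens, all 9 lay above 0 and 2 reached 2-fold, Gbp7 (1.10) and Gbp5 (1.03). Their median was 0.53, above all random lists. Among 28 antiviral genes that type I interferon also induces, 1 reached 2-fold, Cmpk2 (1.01). Their median was 0.04, at the 99.7th percentile, and their mean of 0.19 lay at the 95.9th, inside the middle 95%. None of 23 antigen processing and presentation genes reached 2-fold in either direction (0 higher and 0 lower). Their median was -0.01, at the 77.2nd percentile, with Tap1 at 0.54 and the class II gene RT1-DMb at -0.54.

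Immediate early and stress-activated genes, which respond within minutes to many stimuli, were also higher with IFN-γ. In this list 11 of 24 were at least 2-fold higher and 1 lower, with a median of 0.82 above all random lists. The phosphatase gene Dusp1 was at 2.21, Gadd45b at 2.04 and Junb at 1.94, while Gadd45a was at -1.28. Of 30 reactive astrocyte genes 4 were at least 2-fold higher and 1 lower, with a median of 0.08 above all random lists and a mean of 0.33 at the 99.9th percentile. Its higher members Cxcl10 (1.65) and Ptgs2 (2.68) also belong to the chemokine and NF-κB lists.

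Markers of microglia, the resident macrophages of the brain, were lower beside these groups. Of 19, 18 lay below 0, with a median of -0.42 below all random lists, Cx3cr1 at -1.23, Trem2 and Csf1r both at -0.64, and Ptprc at 0.23. The 24 cell cycle genes all lay below 0, with a median of -0.26 below all random lists and none at 2-fold (0 lower). Astrocyte markers had a median of 0.08 (99.6th percentile, and 68.8th for the mean of the list), with Aqp4, the astrocyte water channel, at 0.53. Neuron markers had a median of 0.13 over 7 genes (98.2nd percentile, and 86.7th for the mean). Cholesterol synthesis genes had a median of -0.13 (2.33rd percentile, but 4.80th after quantile normalization and 9.95th for the mean). Liver X receptor targets had a median of -0.06 at the 27.1st percentile, and at the 0.94th for the mean of -0.14. Lists inside the middle 95% were unfolded protein and heat shock (-0.06), Nrf2 (-0.01), meningeal (0.02), oligodendrocyte (-0.03) and reference genes (-0.01). The signs of the Nrf2 and reference gene medians turned after cyclic loess, that of the reference genes also after median centring, and that of the oligodendrocyte list for the mean.

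Adding GW to IFN-γ went with higher immediate early genes and lower inflammatory genes. Fosb, a subunit of the AP-1 transcription factor, was 14.0-fold higher with GW than with IFN-γ alone, and the activity-regulated gene Arc was 10.7-fold higher. The nuclear receptor genes Nr4a3, Nr4a1 and Nr4a2 were 7.99-fold, 7.24-fold and 6.56-fold higher. Cxcl9, an IFN-γ-induced chemokine gene that recruits T cells, was 7.25-fold lower, and Il1b 3.84-fold lower. Of 11790 genes, 113 were at least 2-fold higher and 112 at least 2-fold lower, with the middle 95% of differences between -0.75 and 0.62 log2.

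Other genes among the 12 highest were Egr4 (3.14), Gadd45g (3.01), Fos (2.97), the heat shock cochaperone gene Dnajb1 (2.87), the matricellular gene Ccn1 (2.75), Garin4 (2.75) and the protease inhibitor gene Tfpi2 (2.65). The lowest differences also included S100a5 (-2.65), the ligand gene Tnfsf18 (-2.50), the lymphoid activation marker Cd69 (-2.46), Plet1 (-2.18), the transcription factor gene Spib (-2.03) and the NF-κB inhibitor gene Tnip3 (-1.95). Cxcr5 (-1.89), the inflammasome gene Nlrp3 (-1.88), Socs1 (-1.87) and Rtp3 (-1.78) completed the 12. Arc and Garin4 with IFN-γ alone and S100a5, Tnfsf18, Plet1 and Spib with GW lay below 5.83, so the size of their differences is uncertain. All 24 immediate early genes lay above 0 and 18 reached 2-fold, with a median of 1.78 above all random lists. Of 18 unfolded protein and heat shock genes 4 were at least 2-fold higher, Dnajb1, Chac1 (2.14), Hsph1 (1.86) and Bag3 (1.46). That list's median of 0.14 lay at the 99.96th percentile.

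The inflammatory lists stood lower. Of 17 chemokine and adhesion genes 5 were at least 2-fold lower and 0 higher, with a median of -0.83 below all random lists. Besides Cxcl9 they included Cxcl11 (-1.65), Cx3cl1 (-1.58) and Cxcl6 (-1.20). Of 28 NF-κB-associated genes 10 were at least 2-fold lower and 0 higher, with a median of -0.60 below all random lists. Il12a (-1.56) and Nos2 (-1.58) were among them, while Il6 (0.49), Lif (0.93) and Ptgs2 (0.93) stood above 0. Il12a lay below 5.83 with GW, at 5.56, so the size of its difference is uncertain. All 9 guanylate-binding protein and GTPase genes lay below 0, with a median of -0.60 at the 0.01st percentile, and Gbp7 (-1.36) reached 2-fold. The same direction held for all 23 antigen presentation genes (median -0.33, 0.01st percentile, lowest the protease gene Ctss at -0.93). It also held for all 28 antiviral genes (median -0.29, 0.03rd percentile, lowest Cmpk2 at -0.99), with 0 at 2-fold in either list. After median centring these medians were -0.25 and -0.21, and members nearest 0, such as B2m (-0.06) and Sp110 (-0.03), would lie above it. Genes of interferon signalling had a median of -0.18 at the 7.53rd percentile, and at the 2.07th after quantile normalization. In that list Socs1 was at -1.87 and Socs3 at 1.76.

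Liver X receptor targets did not stand apart as a list with GW. Their median over 19 genes was -0.15, at the 20.9th percentile, and 1 gene reached 2-fold, the cholesterol transporter gene Npc1 at -1.11. The list also holds the receptor genes Nr1h2 (-0.46) and Nr1h3 (-0.36) themselves. Of the 19, 6 lay above 0 and 13 below. Among those above 0 was Mylip (0.67), which encodes a ligase for the low-density lipoprotein receptor. The lipogenic regulator gene Srebf1 (0.62) and the sterol exporter genes Abcg1 (0.42) and Abca1 (0.22) were others. Thrsp was at -0.73. Cholesterol synthesis genes had a median of -0.09 (32.7th percentile), whose sign turned after cyclic loess, with Insig1, an inhibitor of sterol regulatory element activation, at 1.31.

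Microglia markers were lower again beside the inflammatory genes, with a median of -0.49 below all random lists and 17 of 19 below 0. The signalling adaptor gene Tyrobp was at -1.22 and Ptprc at -1.16, while Cx3cr1 was at 0.68. Which cells of the culture gave the lower inflammatory values was not tested. The remaining lists lay inside the middle 95%: astrocyte (-0.14), reactive astrocyte (-0.11), meningeal (-0.10, and at the 2.06th percentile for the mean of -0.26), oligodendrocyte (-0.02), neuron (0.07), cell cycle (-0.09), Nrf2 (0.03) and reference genes (-0.18). The oligodendrocyte sign turned under all 3 other scalings, and the neuron median was -0.06 without the filter and the neuron mean -0.07. In the Nrf2 list 2 of 13 reached 2-fold, the heme oxygenase gene Hmox1 (1.25) and the metallothionein gene Mt1 (1.19).

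**Figure D2:**
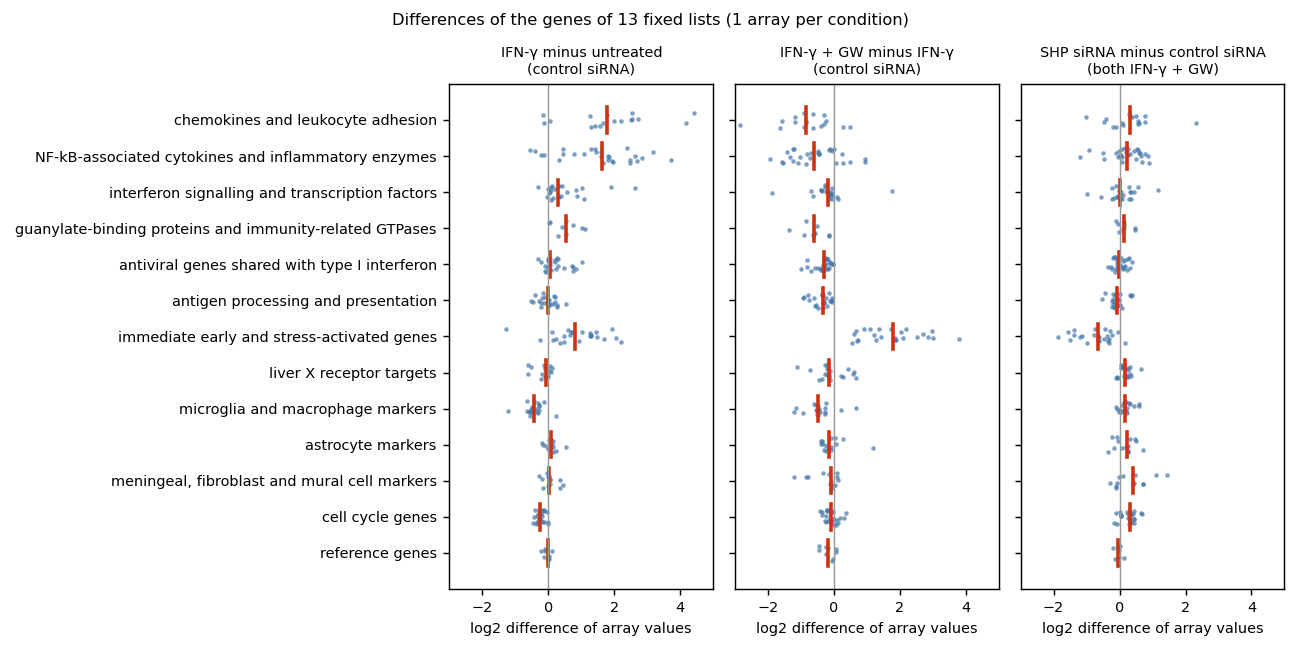
Log2 differences (x axis) of the genes past the filter in 13 fixed lists, for the 3 main comparisons, with 1 point per gene and a red bar at the list median. Immediate early genes have medians of 0.82, 1.78 and -0.64 from left to right, and chemokine and adhesion genes 1.77, -0.83 and 0.32.

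Of the 190 genes at least 2-fold higher with IFN-γ, 62 were at least 2-fold lower with GW, against 1.80 expected for independent lists. Their median difference with GW was -0.73, and 149 lay below 0. Both differences use the IFN-γ array, whose error enters them with opposite signs. Simulated arrays with no GW effect gave a median of -0.07 and at most 2 genes. They took the measured values as true and added array noise, so error already in the measured IFN-γ array stayed in both steps. They may therefore understate what a shared array alone gives. A difference of the IFN-γ culture itself, which could give the same overlap, was not covered. A set chosen without a shared array behaved otherwise. The 188 genes at least 2-fold higher in the SHP siRNA culture with IFN-γ and GW than in the untreated culture had a median of 0.27 with GW, above all random lists. Of these 106 lay above 0 and 82 below, with 60 at least 2-fold higher and 29 at least 2-fold lower. That set holds 20 immediate early genes, and without that list, a choice made after seeing the data, the median of the other 168 was 0.064. Since the set was chosen in a culture that had GW, it takes in genes higher with GW itself.

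SHP siRNA, compared with control siRNA under IFN-γ and GW, gave fewer differences than either treatment. Cxcl9 was 4.96-fold higher with SHP siRNA, at 9.18 against 6.87, near its value of 9.73 with IFN-γ alone. The water channel gene Aqp1 was 2.83-fold higher and Postn, which encodes the matrix protein periostin, 2.69-fold higher. Among lower genes were Egr4 (3.67-fold), Nr4a2 (3.65-fold) and the vesicle protein gene Syt4 (3.33-fold). Of 11790 genes, 17 were at least 2-fold higher and 31 at least 2-fold lower, with the middle 95% of differences between -0.46 and 0.48 log2, and without the filter 27 and 48.

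The other highest genes were Vof16 (1.48), Gmnc (1.19), Socs1 (1.15), the kinase gene Ripk2 (1.14), Cxcr5 (1.13), Akr1b8 (1.12), Msc (1.12), the retinoic acid synthesis gene Aldh1a2 (1.11) and Tnfsf15 (1.09). The lowest also included Arc (-1.72), the Krüppel-like factor genes Klf2 (-1.57) and Klf4 (-1.39), Nr4a3 (-1.52), Nfil3 (-1.44), the activin subunit gene Inhba (-1.43), Fosb (-1.39), Clec2gl1 (-1.39) and the pentraxin gene Ptx3 (-1.23). Akr1b8 with control siRNA and Clec2gl1 with SHP siRNA lay below 5.83, so the size of their differences is uncertain. Immediate early genes were lower as a list, with 7 of 24 at least 2-fold lower, 23 below 0 and a median of -0.64 below all random lists. Unfolded protein and heat shock genes had a median of 0.00 (37.7th percentile) and a mean of -0.21 (0.05th percentile), with Dnajb1 at -1.06.

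The chemokine and NF-κB-associated lists stood modestly higher with SHP siRNA, and the other inflammatory and interferon lists were not called high. Chemokine and adhesion genes had a median of 0.32, above all random lists, with 12 of 17 above 0. Their 2-fold members went opposite ways, Cxcl9 at 2.31 and Ccl5 at -1.03. NF-κB-associated genes had a median of 0.22, above all random lists, with 21 of 28 above 0 and 0 at 2-fold higher. Tnfaip2 and Il1b were both at 0.88, Il12a at 0.77, and Lif, the 1 member at least 2-fold lower, at -1.19. Il12a lay below 5.83 with control siRNA, at 5.56, so the size of its difference is uncertain. Guanylate-binding protein and GTPase genes (0.13, 95.5th percentile), interferon signalling (0.02, 57.1st percentile) and antiviral genes (-0.01, 17.3rd percentile) lay inside the middle 95%. Antigen presentation genes had a median of -0.09 at the 1.23rd percentile, and at the 4.17th for the mean, with the class I gene RT1-N3 at -0.53. Liver X receptor targets had a median of 0.16 at the 99.9th percentile, with 16 of 19 above 0, Thrsp at 0.64 and Pltp at 0.34.

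Markers of several cell types differed beside them. Medians were 0.41 for meningeal, fibroblast and mural cell markers and 0.21 for astrocyte markers, both above all random lists, the former at 0.26 without the filter. Of these 8 of 13 and 10 of 15 lay above 0, with lowest values of -0.30 and -0.34, Aqp4 at 0.71 and the collagen gene Col3a1 at 0.71. Postn and Aldh1a2 belong to the meningeal list. Microglia markers had a median of 0.17 (99.9th percentile) and cell cycle genes of 0.32, above all random lists, with Top2a at 0.69 and Ccna2 at 0.66. Reactive astrocyte genes had a median of -0.07 at the 1.61st percentile. Inside the middle 95% lay oligodendrocyte (0.11), neuron (-0.04), Nrf2 (0.02), cholesterol synthesis (-0.02) and reference genes (-0.04). The Nrf2 and cholesterol synthesis signs turned after cyclic loess and under 1 or more other alternatives, and the antiviral sign for the mean. The farnesoid X receptor and endothelial lists had 3 genes each past the filter and were not summarised. Of the former, the sterol hydroxylase gene Cyp27a1 was at 1.32 with IFN-γ, -1.24 with GW and 0.52 with SHP siRNA, and Abcb4 and Fgf19 were at 0.17 and 0.07 with SHP siRNA. Of the latter, Cdh5 was at 0.55, Flt1 at 0.34 and Slco1a4 at 0.44 with SHP siRNA.

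Of the 17 genes at least 2-fold higher with SHP siRNA, 12 were among the 112 at least 2-fold lower with GW, against 0.161 expected for independent lists. Cxcl9, Socs1, Cxcr5, Ripk2 and Vof16 were among them. Of the 31 lower genes, 23 were among the 113 at least 2-fold higher with GW, against 0.297, including Arc, Egr4, Nr4a2, Nr4a3 and Klf2. These differences share the array with control siRNA, IFN-γ and GW. Simulated arrays with no SHP siRNA effect gave at most 2 genes in either direction. They added only array noise (SD 0.194 log2) to measured values taken as true, so 2-fold steps were rare by construction. Error already in the measured shared array stayed in both steps, so they may understate what sharing it gives. A difference of the shared culture itself was not simulated, and it alone could give both overlaps. The overlaps therefore do not separate an effect of SHP siRNA from such a difference.

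The genes higher with IFN-γ were also followed to SHP siRNA over a pair of arrays with none in common. Of the 190, 136 lay above 0 and 54 below, with a median of 0.30 above all random lists, and 9 were at least 2-fold higher and 7 at least 2-fold lower. Without the immediate early list the median over 179 genes was 0.33. The followed difference subtracts the single control siRNA culture with IFN-γ and GW. There the 190 genes had a median of -0.73 against IFN-γ alone. A difference of that culture itself could give the same direction, so an effect of SHP siRNA is not separated from it. Across all 11790 genes, which are not independent replicates, the IFN-γ and SHP siRNA differences correlated weakly, with Pearson's r of 0.15 and Spearman's rho of 0.08. Of the 5 pairs of differences correlated, the GW difference and that of the SHP siRNA culture over the untreated one, with no shared array, gave 0.40 and 0.47. The remaining pair without a shared array was not in the plan written before the data were examined. It set IFN-γ with GW over untreated against SHP siRNA with IFN-γ and GW over IFN-γ alone, and gave 0.54 and 0.55. In both of these pairs each difference is a GW culture minus a culture without GW. Anything common to the GW cultures would make such correlations positive, so they do not bear on SHP siRNA. The pairs that share an array gave r of -0.23 for IFN-γ with GW and -0.54 for GW with SHP siRNA, where unchanged simulated arrays of equal noise gave -0.50 for both. That value depends on equal noise in all arrays. The covariance of GW with SHP siRNA, -0.0467, was larger in size than in unchanged arrays with the noise of any of the 3 main comparisons (-0.0124 to -0.0375). That of IFN-γ with GW, -0.0268, lay between the simulated values (-0.0124 to -0.0376). The noise of a single array was not measured, and a difference of a shared culture itself was not simulated.

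**Figure D3:**
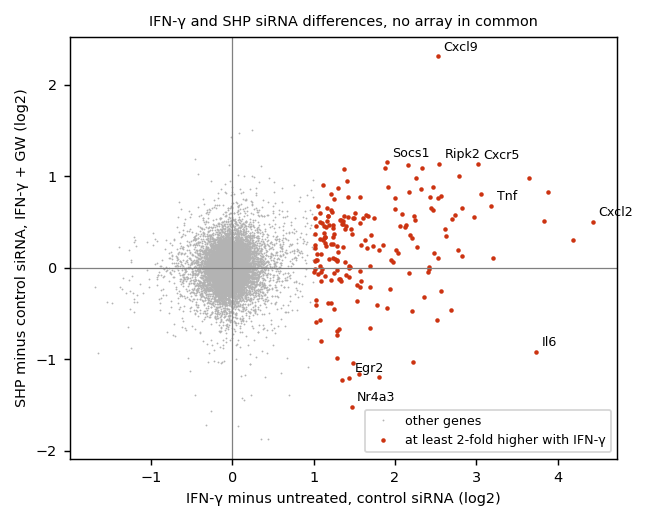
Log2 difference with IFN-γ (x axis) against log2 difference with SHP siRNA (y axis) for 11790 genes, with the 190 genes at least 2-fold higher with IFN-γ in red. Of the red points 136 lie above 0 on the y axis and 54 below, with Cxcl9 highest at 2.31 and Nr4a3 at -1.52.

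Set against the untreated culture, the culture with IFN-γ and GW had 194 genes at least 2-fold higher and 99 lower, and the SHP siRNA culture with both had 188 and 104. Of the 190 genes higher with IFN-γ alone, 87 were also at least 2-fold higher in the former and 118 in the latter. All these differences subtract the same untreated array, whose error favours such overlaps, and these were not simulated. Chemokine and adhesion genes had medians of 0.63 and 1.11 over the untreated culture in these cultures, and NF-κB-associated genes 0.78 and 1.03. Immediate early genes had medians of 2.60 and 2.05, and antigen presentation genes -0.36 and -0.58. Against IFN-γ alone the SHP siRNA culture had 53 genes higher and 48 lower. With each array centred on its median these 3 splits were 222 and 64, 226 and 65, and 67 and 34, and after cyclic loess the second was 220 and 72.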

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

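The tests with cyclic loess below were set before any loess value was seen, and all other tests in this part were chosen after the result they bear on was seen. Among 3338 probes past the filter that carry no gene name here, 25 were at least 2-fold higher with IFN-γ than in the untreated culture and 6 lower. They are listed because they belong to data outside the comparisons of genes. No explanation was tested for them.

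NF-κB-associated genes had a median of 1.64 with IFN-γ, while antiviral and antigen presentation genes, which type I and type II interferons commonly induce, had medians of 0.04 and -0.01. A ceiling of the measurement near the antiviral median of 9.84 is argued against. The 13 NF-κB-associated and chemokine genes that started at or above it had a median of 1.28, and 8 reached 2-fold. The highest antiviral genes, such as Mx1 at 12.20 and Samd9l at 11.97, are not covered. Of the 13, Lcn2 (12.20) and Cxcl16 (11.59) started highest, and they differed by -0.41 and 0.05. These 4 genes are named for their level, outside the rule. An intensity-dependent difference between arrays is argued against, since the NF-κB-associated list kept a gap of 1.58 over the antiviral list after cyclic loess. More microglia in the IFN-γ culture was not decided. Their markers' median was -0.42, with 18 of 19 below 0. Lower transcription within microglia could lower that median whatever their number. Prior induction of the antiviral genes, for example by transfection, was not decided. Their untreated median lay at the 93.5th percentile of named genes, but reference genes stood at the 96.1st, so a level on the array does not show induction, and no culture without siRNA was analysed here; a first version of this test, against random lists, was dropped because the NF-κB-associated list also stood high in it, at the 99.8th percentile against 100. A response to IFN-γ itself, to another stimulus added with it, or in microglia already present in the culture stays open and untested.

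Microglia and macrophage markers stood at a median level of 9.82 in the untreated culture, with Fcer1g at 12.05 and Lyz2 at 11.88 (named for their level, outside the rule), although the serum-free step was meant to remove these cells, and they were lower with IFN-γ (-0.42) and lower again with GW (-0.49). A scaling difference common to all cell types is argued against, since after cyclic loess they stayed below the astrocyte markers by -0.50 with IFN-γ and -0.33 with GW. A smaller share of microglia would lower all 19 markers by a like amount, and the spread over the markers was unremarkable, at the 58.5th percentile of random lists with IFN-γ and the 76.3rd with GW. A lower share could therefore not be separated from lower transcription within microglia. Ptprc at 0.23 with IFN-γ, and Cx3cr1 at 0.68 and Tmem119 at 0.21 with GW, went the other way. Loss of microglia during the experiment, their response to the treatments, and cultures that differed from the start are candidate explanations.

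Immediate early genes had a median of 1.78 with IFN-γ and GW over IFN-γ alone. An intensity-dependent difference between arrays is argued against by a median of 1.87 after cyclic loess. An event in the control siRNA culture alone is argued against as the whole cause, since the list's median in the SHP siRNA culture with IFN-γ and GW over IFN-γ alone was 0.88. A difference in culture or handling common to both GW cultures cannot be told apart from GW, since 1 array per culture gives no replicate that would separate them. The median of -0.35 for genes with respiratory chain symbols decides nothing here, because that class was chosen after it was seen to stand apart with GW. An effect of GW itself stays open and untested, and would need replicate cultures and GW without IFN-γ.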

How the results depend on the processing

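No paired analysis was possible because each group has 1 array. All 18 values of the 3 correlations without a shared array moved by under 0.1, most without the filter (0.44 for the pair at 0.54). Of 3798 values of named genes 2 moved by more than the robust spread of differences, both with the mean of a gene's probes: Mbp with IFN-γ (-0.17) and Mt1 with GW (1.58). With any scaling the median of all genes stayed between -0.05 and 0.03 with IFN-γ, GW and SHP siRNA.

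Counts are higher and lower genes, in the order IFN-γ, GW, SHP siRNA, IFN-γ with GW over untreated, SHP siRNA over untreated, SHP siRNA over IFN-γ. At 1.5-fold they were 356 and 187, 332 and 586, 168 and 142, 466 and 781, 480 and 734, 236 and 438. At 3-fold they were 80 and 2, 50 and 26, 1 and 4, 105 and 4, 96 and 10, 17 and 7, as a threshold's construction implies. Median centring shifts all differences of a comparison by 1 constant. Over untreated it gave fewer lower genes (64 and 65) and more higher genes (222 and 226). No filter gave 27 and 48 for SHP siRNA, since it tests more genes. The other 35 of 48 higher and 33 of 48 lower counts stayed within 1.5 times.

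Of 399 list values, 387 moved by under 1.96 SDs of random medians. That limit was chosen after seeing that 57 moved by over 1 SD. The cause of the 12 moves was not tested. Without the filter chemokine genes had 1.61 (IFN-γ) and -0.63 (GW) and meningeal markers 0.26 (SHP siRNA). As means, with IFN-γ, interferon signalling had 0.48, chemokines 1.87, antiviral genes 0.19, NF-κB-associated genes 1.52, liver X receptor targets -0.14 and reactive astrocyte genes 0.33. With GW, unfolded protein genes had 0.50, and with SHP siRNA -0.21, where immediate early genes had -0.74.

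The GW median of the set chosen on SHP siRNA over untreated was 0.33 with quantile normalization and median centring, 0.34 with cyclic loess, 0.21 at 1.5-fold, 0.48 at 3-fold and 0.064 without immediate early genes (a choice made after seeing the data). It reversed to -0.73 for the set chosen on the shared IFN-γ array. That is a partly different set of 190 genes, chosen on cultures without GW, of which 118 were among the 188. The SHP siRNA median of the IFN-γ set was 0.26 without the filter, 0.20 at 1.5-fold, 0.43 at 3-fold, 0.33 without immediate early genes and 0.16 for the set on the shared SHP siRNA array, whose error enters with the same sign. The causes were not tested. Signal over background is unknown, which limits genes below 5.83, Nr0b2 among them.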

Other observations

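Other gene classes, chosen after seeing the data, also stood apart with GW. They were taken by the start of the gene symbol, so they can hold related genes, such as assembly factors and kinases, that are not subunits. Histone genes (23 past the filter) had a median log2 difference of 0.72 with GW, above all 10000 random lists, after -0.20 with IFN-γ, and 0.01 with SHP siRNA. In the SHP siRNA culture with IFN-γ and GW they stood at 0.58 over IFN-γ alone. The mitochondrial respiratory chain class, which takes in ATP synthase genes (89 genes), had a median of -0.35 with GW, below all random lists. It had -0.09 for IFN-γ and -0.04 for SHP siRNA. In the SHP siRNA culture over IFN-γ alone it stood at -0.36. The class with ribosomal protein symbols (118 genes) had -0.11 with IFN-γ, -0.19 with GW and 0.14 with SHP siRNA.

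Among genes higher with IFN-γ, 17 were at least 2-fold higher again with GW, against 1.82 expected for independent lists. The IFN-γ array enters these differences with opposite signs, and this overlap was not simulated. They included Nr4a1, Nr4a3, Dusp1, Fosl1 and Ptx3. Il6 and Lif stood apart from most NF-κB-associated genes in the same way, without a second 2-fold step. Il6 had log2 values of 6.72, 10.45, 10.95 and 10.03 in the untreated, IFN-γ, IFN-γ with GW and SHP siRNA cultures, and Lif 8.22, 10.02, 10.95 and 9.76. Ccl5 went 10.89, 10.76, 10.13 and 9.10, lower in each culture in turn. Probes with no gene name gave 43 at least 2-fold higher and 28 lower with GW, and 6 and 11 with SHP siRNA.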
